A study of Mus musculus with 6 samples.

How the data were processed

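The data are RNA-seq gene counts of 6 libraries of primary wild-type mouse myeloid cells, 3 control and 3 treated with TMAO, all labelled 24 h. Per the labels' protocols, total RNA was extracted with TRIzol, poly(A) RNA was selected with oligo(dT) beads and fragmented, cDNA was primed with random hexamers, and paired-end libraries were amplified by PCR. The protocol names sequencers of 2 makers without saying which library ran on which, so a sequencing batch was not analysed here, and a platform difference between the groups, if there was one, cannot be told apart from the treatment in any of the calls. The authors deposited 1 table of raw counts per Ensembl gene for the 6 libraries, with whole numbers and no normalization. The genome build was GRCm39, per the submitters' processing notes; the aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here. Without a stated strand setting, counts of overlapping and antisense genes cannot be told apart. Members of families with near-identical copies (such as the Stfa, Oas, Ifit, Ly6, Ear, histone, ribosomal protein and immunoglobulin genes) are uncertain, since their reads may have been split or lost in counting.

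Groups and replicate numbers were taken from the sample titles, and table columns were matched to samples by the deposited sample descriptions, which name the control samples Control and the treated samples T-BMDM. The labels do not explain this difference in naming, so a difference between the groups in how the cells were obtained cannot be told apart from the treatment. Library totals ran from 37759007 to 41735109 counts. Counts of each pair of libraries in a group were compared by a chi-square over genes, and the statistic per degree of freedom was 14.2 to 72.6, so no pair agreed within sampling noise. Of the 25751 gene IDs, 25386 were given symbols from the GENCODE annotation of the older build GRCm38, matched by ID, and 365 had none. That annotation was used only for symbols and for the length and GC content of each gene's longest transcript, and no coordinates are printed because its build is not the authors'.

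Genes were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): filterByExpr by group with its minimum count of 10 kept 14626 genes, TMM factors scaled the libraries, and a quasi-likelihood F test compared TMAO with control without covariates. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. CPM values are scaled by TMM, errors are SD over 3 libraries, and the SE of a log2 fold change is the estimate divided by the square root of its F value. A fold against a group with no counts uses a floor of 3 counts over the group, and ratios with 1 to 3 counts carry an exact 95% binomial interval; both cover counting error only. The design asked for the defaults of edgeR, and the alternatives written beforehand took the legacy moderation of the quasi-likelihood as a departure from them. In the installed version the legacy moderation is the default, so it is the setting reported, and the newer moderation became the alternative; both counts of genes had been seen when this was settled.

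Before the data were examined, 47 gene lists were fixed, with the rule for named genes. The rule takes 7 genes of the TREM-1 and inflammasome pathway and, among called genes with a mean of at least 5 CPM, a gene symbol that is not a model name and no overlap between groups, the 10 with the highest and the 10 with the lowest log2 fold change. It also takes the members of each list with the smallest p, up to 4 in called lists and up to 2 in the others. Some genes examined are not reported here. Lists with at least 5 tested members (45 lists) were tested, two-sided, by camera from limma with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Aldoa could not be placed by symbol and was left out, and Ero1a was placed by its older symbol Ero1l. A further 7 lists were written after the first results were seen and are used only in the closing section.

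The steps were tested on simulated data. In counts simulated for this comparison over 14327 genes, edgeR called 66.0% of 50 genes changed 1.5-fold, 96.0% of 50 changed 2-fold, all 50 changed 4-fold and all 50 changed 8-fold, and 0.0637% of 14127 unchanged genes. In simulated lists over 14626 genes, camera called 10 of 10 shifted and 1 of 190 unshifted lists. The simulated genes were drawn independently and without a length trend, and 200 were changed in the gene simulation. In the data, 65.7% of the genes tested changed, and the correlation estimated within the type I interferon list was 0.72. These rates therefore do not give the error rates of the real calls. Alternatives were DESeq2 1.42.0, limma-voom, robust and newer quasi-likelihood moderation, other normalizations and count filters, the 20 most abundant genes left out, a test against a fold of 1.5, the replicate number as a block, trends on gene length and GC content removed by offsets, and each library left out in turn. For lists they also included an estimated correlation, fry, and members in only 1 list. Length and GC values covered 99.8% of the genes tested.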

Results

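Gene counts were collected by poly(A)-selected, paired-end RNA-seq from primary wild-type mouse myeloid cells at 24 h, in 3 control libraries and 3 libraries of cells treated with trimethylamine N-oxide (TMAO). TMAO is made in the liver from trimethylamine, which gut bacteria release from dietary choline and carnitine. The control libraries held 38233772, 41735109 and 40373981 counts and the TMAO libraries 38875877, 37759007 and 38935691, over a table of 25751 genes. CPM values are counts scaled to a common library size with TMM factors. On log2 CPM, libraries of the same group correlated across genes at r = 0.9828 to 0.9901 and libraries of different groups at 0.8972 to 0.9299. The first principal component held 84.0% of the variance and separated the 2 groups. The labels do not say whether the libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical. Nor do they say whether control and treated cells came from the same culture and stage of differentiation.

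The comparison of TMAO with control asked which transcripts differ in treated myeloid cells, with Trem1 and Nlrp3 as the genes the series is named for. Trem1, a receptor that amplifies inflammatory signalling in myeloid cells, rose from 2.13 ± 0.628 CPM in controls to 134 ± 10.1 CPM with TMAO (mean ± SD, n = 3 per group). Nlrp3, the sensor of the NLRP3 inflammasome, rose from 63.1 ± 3.64 to 433 ± 65.2 CPM, and Il1b, the cytokine precursor that caspase-1 cleaves, rose from 15.6 ± 4.06 to 903 ± 11.2 CPM. Genes of granulocyte precursors and of mitosis rose with them: Mpo went from 0.0413 ± 0.0149 to 158 ± 14.9 CPM and Top2a from 7.94 ± 0.823 to 59.7 ± 4.49 CPM. Interferon-stimulated genes fell, among them Oas3, from 336 ± 48.6 to 28.6 ± 1.02 CPM. In all, 9608 of 14626 genes tested changed at an adjusted p under 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 4830 higher and 4778 lower. Of these, 4448 changed at least 2-fold, 2291 higher and 2157 lower. In 71.0% of the genes tested the CPM values of the groups did not overlap, where chance gives 10%.

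In the TREM and inflammasome pathway, the receptor, the sensor and the cytokine rose while the adaptor and the protease fell. The log2 fold change of Trem1 (ENSMUSG00000042265) was 5.98 (SE 0.19, edgeR adjusted p = 7.84e-09), that of Nlrp3 (ENSMUSG00000032691) was 2.78 (SE 0.12, edgeR adjusted p = 4.32e-08) and that of Il1b was 5.85 (SE 0.19, edgeR adjusted p = 7.84e-09). Casp1, the inflammasome protease, fell from 78.7 ± 0.776 to 57.5 ± 7.95 CPM (log2 fold change -0.45, SE 0.11, edgeR adjusted p = 0.0034). Pycard, the adaptor between sensor and protease, fell from 21.9 ± 2.29 to 15.4 ± 3.60 CPM (log2 fold change -0.50, SE 0.16, edgeR adjusted p = 0.0193). Il18 was at 8.76 ± 0.468 and 11.2 ± 2.51 CPM and Gsdmd, the pore-forming protein, at 101 ± 3.06 and 88.4 ± 4.73 CPM, and neither passed the test (edgeR adjusted p = 0.0804 and 0.0664). The 19 members of the inflammasome list moved both ways: 7 rose and 8 fell, and the list as a whole was not called (camera adjusted p = 0.643). Adjusted over the list alone, its counts were also 7 and 8. Of the 12 TREM receptors and adaptors, 5 rose and 2 fell (5 and 1 adjusted over the list alone). The list was called higher (camera adjusted p = 0.00915), at a median log2 fold change of 0.203. That call was lost with correlation estimated from the data (adjusted p = 0.235 with an estimated correlation). Pglyrp1, a ligand of TREM-1, rose 37.9-fold, Trem3 6.56-fold and Card9 1.63-fold. Among members named after their values were seen, Syk fell (log2 fold change -0.58), and Tyrobp, Hcst and Plcg2 did not pass the test. The neutrophil markers rose in the same 3 libraries as Trem1 and Pglyrp1, by a median of 5.42 on the log2 scale.

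**Figure D1:**
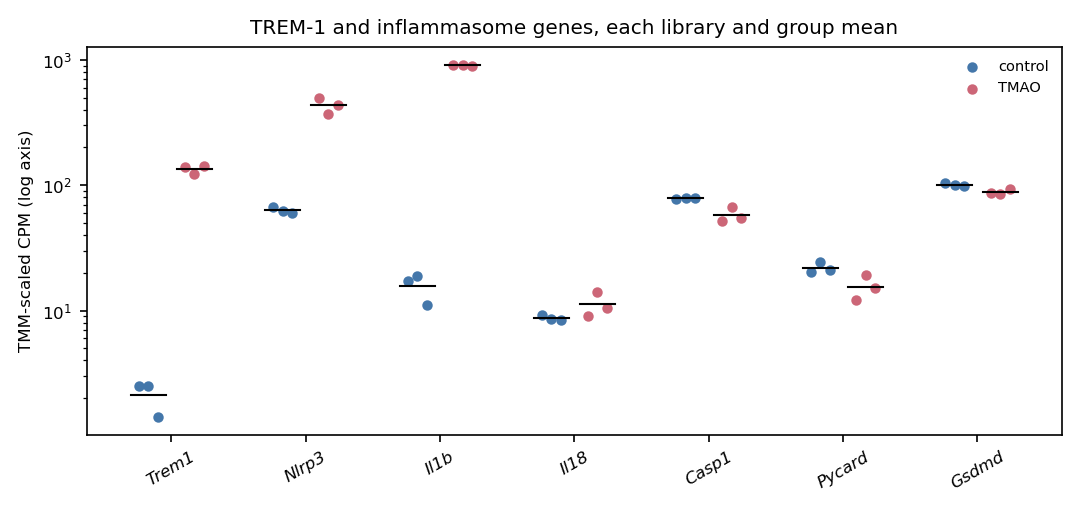
TMM-scaled CPM (log axis) of 7 genes of the TREM-1 and inflammasome pathway in the 3 control and 3 TMAO libraries; points are libraries and bars are group means. Trem1, Nlrp3 and Il1b lie above all controls in every TMAO library, with means of 134, 433 and 903 CPM against 2.13, 63.1 and 15.6 CPM.

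The calls of Casp1 and Pycard depended on how trends across genes were treated. Short genes were higher and long genes lower with TMAO: the median log2 fold change was 0.49 in the shortest 20% of genes and -0.53 in the longest 20%. With the trend on GC content removed, Casp1 was not called (log2 fold change -0.17, adjusted p = 0.168 by edgeR), and with the length trend removed its log2 fold change was -0.82 (range of the adjusted p over the alternatives 1.78e-07 to 0.168). Pycard was not called with the length trend removed (adjusted p = 0.0719 by edgeR), with the GC trend removed (0.0659), without control replicate 2 (0.0797) or without TMAO replicate 3 (0.0642). Its log2 fold changes there were -0.38, -0.39, -0.41 and -0.48, against -0.50 in the main fit, so it stayed lower. The range of its adjusted p over the alternatives was 0.000384 to 0.0797. Gsdmd was called lower without the length trend (log2 fold change -0.48, adjusted p = 0.000172 by edgeR), without the GC trend (0.00137) and with library size as the only scaling (0.049; range over the alternatives 2.45e-05 to 0.19). The GC correction was chosen after the data were seen. Il18 was called higher with the GC trend removed (adjusted p = 0.026 by edgeR) or without TMAO replicate 1 (0.0137), but its direction turned, without a call, with the length trend removed (log2 fold change -0.12, adjusted p = 0.44 by edgeR); the range over its alternatives was 0.0137 to 0.466.

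Inflammatory cytokines and chemokines rose almost as a set. Of 28 members, 27 rose and none fell, also when adjusted over the list alone (camera adjusted p = 1.32e-40), with a median log2 fold change of 3.12. The neutrophil chemokine gene Cxcl2 rose from 22.9 ± 3.41 to 1487 ± 50.6 CPM, Il1a from 5.13 ± 0.775 to 255 ± 10.9 CPM, Osm from 6.36 ± 0.564 to 183 ± 5.05 CPM and Tnf from 86.2 ± 1.83 to 593 ± 6.33 CPM. Il23a, a subunit of interleukin-23, had 1 count in all control libraries and 1553 in the TMAO libraries, a ratio of 1650 (95% counting interval 296 to 65200). Ccl5, named after its value was seen, did not pass the test (log2 fold change -0.04). Among 22 feedback genes and targets of NF-kB, the main transcription factor of inflammatory signalling, 21 rose and none fell, also adjusted over the list alone (camera adjusted p = 7.59e-16). Traf1 rose from 33.0 to 270.2 CPM, Ier3 9.50-fold, Nfkbib 5.45-fold and Bcl3 3.05-fold. Both calls held with an estimated correlation (adjusted p = 0.0383 and 0.0430). Of 23 immediate early genes, which respond first to a stimulus, 21 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 4.78e-18; adjusted p = 0.0457 with an estimated correlation). Fosb rose from 0.0418 ± 0.039 to 13.5 ± 2.41 CPM, Egr1 27.5-fold, Dusp1 8.88-fold and Myc 6.11-fold. In the libraries where these 3 lists were higher, neutrophil and monocyte markers were higher too, with median log2 fold changes of 5.42 and 1.14.

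Markers of classical and alternative macrophage activation both rose. Of 16 classical markers, 12 rose and none fell (14 and 0 adjusted over the list alone; camera adjusted p = 2.74e-14). That call was lost with an estimated correlation (adjusted p = 0.0591 with an estimated correlation). Ptgs2, the inducible cyclooxygenase, rose 57.6-fold and the costimulatory gene Cd86 8.51-fold. Of 19 alternative markers, 12 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 5.52e-06; adjusted p = 0.0457 with an estimated correlation). Chil3 rose 36.4-fold, and Tgm2 and Klf4 had log2 fold changes of 3.59 (SE 0.10) and 2.63 (SE 0.11). Chil3 is also in the list of monocyte markers, and monocyte and neutrophil markers rose in the same libraries, by medians of 1.14 and 5.42 on the log2 scale. Of 29 Toll-like receptor pathway genes, 11 rose and 12 fell, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.622). Tlr2 rose 7.40-fold and its co-receptor Cd14 7.14-fold, whereas Tlr8, a sensor of RNA in endosomes, fell from 184 ± 35.7 to 9.95 ± 6.63 CPM.

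Type I interferon response genes moved the other way. Of 32 members, 28 fell and 2 rose (28 and 3 adjusted over the list alone), with a median log2 fold change of -1.54 (camera adjusted p = 4.56e-14). That call was lost when the correlation of its genes was estimated (adjusted p = 0.284 with an estimated correlation). Oas3 and Oas2, which make the activator of RNase L, had log2 fold changes of -3.56 (SE 0.12) and -2.34 (SE 0.12), Oasl2 of -3.05 (SE 0.11) and Trim30a of -2.19 (SE 0.10). Ddx60, another interferon-stimulated gene, fell from 33.1 ± 3.66 to 2.70 ± 0.384 CPM. The members that rose were Cxcl10 and Mx2, named here after their values were seen, with log2 fold changes of 2.75 and 0.40. Neutrophil and monocyte markers moved up in the libraries where the interferon genes were lower, by medians of 5.42 and 1.14 on the log2 scale. Of 21 interferon-gamma and guanylate-binding protein genes, 11 fell and 5 rose, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.0716). It was called lower without control replicate 3 (adjusted p = 0.017) and with the length trend removed (0.0369; range over the alternatives 0.017 to 0.654). Irgm1 and Irgm2 had log2 fold changes of -1.71 and -1.91. MHC class II genes rose: 9 of 12 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.00689). That call was lost with an estimated correlation (adjusted p = 0.473 with an estimated correlation). Removing the length trend also ended it (camera adjusted p = 0.0744), although the median log2 fold change was then 1.25, against 1.22 in the main fit. The adjusted p ranged over the alternatives from 0.00197 to 0.473. H2-Ab1 rose 3.90-fold and H2-Eb1 6.18-fold, H2-Ob went from 0.0504 ± 0.0515 to 4.28 ± 0.428 CPM, and the protease gene Ctss fell from 5524 ± 221.9 to 2532 ± 128 CPM. B cells also express H2-Ob, and their markers rose in the same libraries by a median of 4.07 on the log2 scale. That median was 2.28, without a call, with a filter of 1 CPM in 3 libraries.

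Most neutrophil and monocyte markers rose with TMAO. Of 20 neutrophil markers, 18 rose and 1 fell, also adjusted over the list alone, with a median log2 fold change of 5.42 (camera adjusted p = 5.05e-41; adjusted p = 0.0383 with an estimated correlation). The granule protease genes Elane, Ctsg and Prtn3 rose from 0.101 ± 0.103 to 234 ± 35.2 CPM, from 0.0564 ± 0.0503 to 52.2 ± 5.19 CPM and from 0.360 ± 0.108 to 71.3 ± 8.95 CPM. Ngp, a granule protein gene, reached 1164 ± 80.1 CPM against 7.50 ± 1.73 CPM in controls, Fcnb rose from 0.0993 ± 0.0282 to 37.5 ± 4.01 CPM and Ms4a3, a gene of granulocyte and monocyte progenitors, from 0.0333 ± 0.0289 to 18.4 ± 2.73 CPM. The median log2 CPM of the neutrophil markers lay between -1.27 and -0.94 in the control libraries and between 5.74 and 6.04 in the TMAO libraries. Myl10 had no counts in the controls and 1768 in the TMAO libraries, at least 626-fold higher against a floor of 3 counts over the group. Of 17 monocyte markers, 14 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 5.76e-11; adjusted p = 0.0591 with an estimated correlation, which ends the call). The median log2 fold change of the monocyte markers was 1.14, and it ran from 0.43 to 1.55 over the alternatives. F13a1 rose 20.2-fold and Plac8 34.1-fold.

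**Figure D2:**
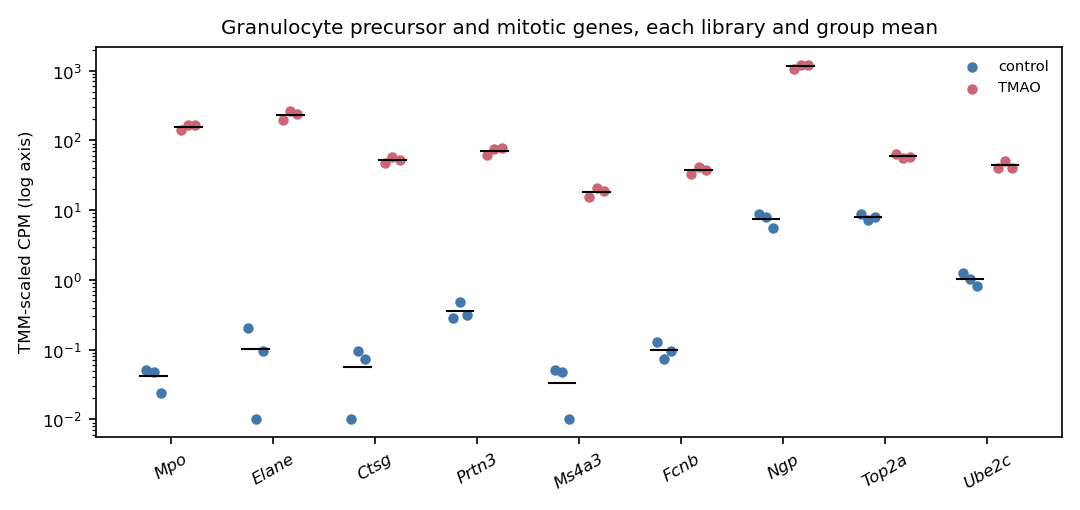
TMM-scaled CPM (log axis) of 7 granulocyte precursor genes and the mitotic genes Top2a and Ube2c in the 3 control and 3 TMAO libraries; points are libraries, bars are group means, and a library with 0 counts is drawn at 0.01 CPM. Every TMAO library lies above every control for all 9 genes, with Ngp at a mean of 1164 CPM against 7.50 CPM.

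Lists of B cell, erythroid and megakaryocyte, and dendritic cell markers were also higher. Of 10 B cell markers, 8 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0109). The call was lost with an estimated correlation (adjusted p = 0.19 with an estimated correlation). A filter of 1 CPM in 3 libraries also ended it (camera adjusted p = 0.0652, at a median log2 fold change of 2.28). The adjusted p ranged over the alternatives from 0.000114, by fry, which does not set a list against other genes, to 0.19. The B cell median log2 fold change was 4.07, and 3.67 with the 2 members that had no control counts set at their bound. Igkc had 2 control and 723 TMAO counts (ratio 384, 95% counting interval 106 to 3180). Of 11 erythroid and megakaryocyte markers, 7 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.00113; adjusted p = 0.0971 with an estimated correlation, which ends the call). The platelet chemokine gene Pf4 rose from 50.9 ± 10.6 to 383 ± 94.3 CPM and Itga2b 10.5-fold. Of 17 dendritic cell markers, 11 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.00606; adjusted p = 0.224 with an estimated correlation, which ends the call). Its median log2 fold change was 2.38, also with the 1 member that had no control counts at its bound, and Ccl22 rose 12.5-fold and Itgax fell with a log2 fold change of -1.30. Lists not called were T and NK cell markers (5 of 7 rose, 1 fell; camera adjusted p = 0.0792), eosinophil markers (4 of 5 rose, 1 fell; 0.120), stromal and endothelial markers (4 of 15 rose, 2 fell; 0.837) and osteoclast markers (7 of 12 rose, 4 fell; 0.622). Adjusted over the list alone, only the osteoclast counts differed among these 4 lists, with 7 and 5. The T and NK list was called higher with the GC trend removed (adjusted p = 0.0463; range over the alternatives 0.00067, by fry, to 0.304). Prg2, an eosinophil granule gene, had 3 control and 756 TMAO counts (ratio 268, 95% counting interval 91.3 to 1300) and Nkg7 had 0 and 224, at least 79.4-fold higher. Of 4 mast cell and basophil markers, too few for a list test, 3 rose and 1 fell, also adjusted over the list alone, with Hdc 23.5-fold higher.

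Macrophage identity genes moved in both directions: of 21 members, 6 rose and 9 fell, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.0635). It was called lower without control replicate 1 (adjusted p = 0.0447), without control replicate 3 (0.0337), without TMAO replicate 2 (0.0317), and with the length (0.0177) or GC trend (0.0226) removed, with a range over the alternatives of 0.000822, by fry, to 0.295. Cd14 was among those that rose, and the Fc receptor gene Fcgr1 fell from 251 ± 27.5 to 59.9 ± 0.91 CPM. Complement and efferocytosis genes, which serve the clearance of dying cells, fell in 11 of 22 cases and rose in 5, also adjusted over the list alone (camera adjusted p = 0.0092). The call was lost with an estimated correlation (adjusted p = 0.189 with an estimated correlation) and without the members shared with another list (0.0673; range over the alternatives 0.000211, by fry, to 0.189). Mertk, a receptor for apoptotic cells, fell from 162 ± 15.8 to 16.3 ± 3.67 CPM, and Mfge8 and C3ar1 had log2 fold changes of -1.44 and -1.25. In the libraries where these genes fell, neutrophil and monocyte markers rose, by medians of 5.42 and 1.14 on the log2 scale. Of 33 lysosome and autophagy genes, 19 fell and 8 rose, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.0716). It was called lower without control replicate 3 (adjusted p = 0.0364) and with the GC trend removed (0.0289; range over the alternatives 0.000924, by fry, to 0.473). Atp6v0d2 fell with a log2 fold change of -2.82, whereas Sqstm1, an autophagy receptor, rose from 895 ± 52.0 to 5063 ± 104.2 CPM. Of 20 chemokine and adhesion receptors, 10 rose and 6 fell (11 and 6 adjusted over the list alone; camera adjusted p = 0.106), with Ccr1 5.43-fold higher.

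The genes with the lowest log2 fold changes under the naming rule were Mill2 (-5.96, SE 0.23), Mamdc2 (-5.53, SE 0.17), H2-T24 (-4.31, SE 0.15), Tlr8 (-4.20, SE 0.40), Pdpr (-4.00, SE 0.38), Fam171a1 (-3.84, SE 0.28), Atp7a (-3.84, SE 0.49), Lpar5 (-3.79, SE 0.27), Ddx60 (-3.61, SE 0.15) and Oas3 (-3.56, SE 0.12). Mill2 and H2-T24 encode MHC class I-like molecules, and Atp7a encodes a copper transporter. Mill2 fell from 12.8 ± 0.371 to 0.203 ± 0.0859 CPM. The TMAO libraries varied widely in Atp7a (4.99 ± 4.31 CPM), Tlr8 (9.95 ± 6.63 CPM) and Pdpr (1.70 ± 1.07 CPM), and without TMAO replicate 1 their log2 fold changes were -4.81, -4.86 and -4.65.

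Genes of the integrated stress response, driven by the transcription factor ATF4, rose as a set. Of 26 members, 23 rose and 1 fell, also adjusted over the list alone, with a median log2 fold change of 2.46 (camera adjusted p = 1.71e-27; adjusted p = 0.0383 with an estimated correlation). Atf4 rose from 185 ± 6.97 to 879 ± 34.5 CPM, Asns, the asparagine synthetase gene, 10.7-fold, Atf5 8.71-fold and Ppp1r15a 6.37-fold. Neutrophil and monocyte markers were higher in the same libraries as the stress genes, by medians of 5.42 and 1.14 on the log2 scale. Chaperones of the endoplasmic reticulum did not move as a set: 11 of 24 rose and 7 fell (12 and 7 adjusted over the list alone; camera adjusted p = 0.646), with Herpud1 2.94-fold higher and Atf6 at a log2 fold change of -1.14. Of 21 heat shock genes, 10 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.368), with Hsf1 1.94-fold higher. Of 27 NRF2 antioxidant genes, 14 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.000645; adjusted p = 0.27 with an estimated correlation, which ends the call). Hmox1, the haem oxygenase gene, rose from 516 ± 26.1 to 2354 ± 68.1 CPM, the cystine transporter gene Slc7a11 5.54-fold and Srxn1 3.26-fold. Of 18 genes of osmotic stress and osmolyte transport, 9 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.323), with Aqp9 32.1-fold and Slc38a2 2.80-fold higher. That list was called higher with the length trend removed (adjusted p = 0.0235; range over the alternatives 0.00679, by fry, to 0.559). Of 15 metallothionein and iron genes, 6 rose and 6 fell (6 and 7 adjusted over the list alone; camera adjusted p = 0.696), with Lcn2 8.52-fold higher and Tfrc at a log2 fold change of -1.60. Of 14 NADPH oxidase and mitochondrial ROS genes, 6 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.826), and Cybb, the oxidase's catalytic subunit, fell from 2785 ± 243.2 to 858 ± 46.5 CPM.

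Mitosis genes rose throughout. All 31 G2/M genes tested rose, also adjusted over the list alone, with a median log2 fold change of 2.91 (camera adjusted p = 4.91e-33; adjusted p = 0.0425 with an estimated correlation). Ube2c rose 42.2-fold, Kif2c 24.4-fold, Plk1 15.7-fold and Top2a 7.51-fold. Neutrophil markers and monocyte markers rose in the same libraries, by medians of 5.42 and 1.14 on the log2 scale. Of 29 genes of G1/S and DNA replication, 18 rose and 5 fell (19 and 5 adjusted over the list alone; camera adjusted p = 0.0131). That call was lost with an estimated correlation (adjusted p = 0.303 with an estimated correlation). Rrm2 rose 5.76-fold and Cdc45 4.62-fold. Of 20 p53 targets and cell death genes, 12 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.0311). The call was lost with an estimated correlation (adjusted p = 0.175 with an estimated correlation) and without control replicate 1 (0.0525; range over the alternatives 1.51e-05, by fry, to 0.175). Gdf15 rose 7.82-fold and the cell cycle inhibitor gene Cdkn1a 3.91-fold, and Sesn1 fell with a log2 fold change of -2.97.

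In energy metabolism, glycolysis genes rose and fatty acid oxidation genes fell. Of 27 glycolysis and HIF-1 target genes, 22 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 1.44e-06; adjusted p = 0.175 with an estimated correlation, which ends the call). Vegfa rose 6.88-fold, Egln3, an oxygen-sensing hydroxylase gene, 3.60-fold and the glucose transporter gene Slc2a1 3.02-fold. Of 19 fatty acid oxidation and PPAR target genes, 16 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0104; adjusted p = 0.133 with an estimated correlation, which ends the call). Cpt1a, which controls entry of fatty acids into mitochondria, fell with a log2 fold change of -1.60 (SE 0.11). The libraries with these metabolic changes also held more neutrophil and monocyte transcripts, with median log2 fold changes of 5.42 and 1.14 over the marker lists. Of 13 mitochondrially encoded genes, 11 fell and none rose, also adjusted over the list alone (camera adjusted p = 0.00284). The call was lost with an estimated correlation (adjusted p = 0.304 with an estimated correlation) and with the GC trend removed (0.117; range over the alternatives 3.69e-06 to 0.304). They took 3.25% to 3.64% of the counts in control libraries and 1.77% to 2.06% in TMAO libraries, and mt-Cytb and mt-Nd2 had log2 fold changes of -0.95 and -1.18. Of 42 nuclear genes of oxidative phosphorylation, 29 rose and 1 fell (30 and 1 adjusted over the list alone; camera adjusted p = 0.023), with Uqcrq 2.82-fold and Uqcrfs1 1.75-fold higher. The call was lost with an estimated correlation (adjusted p = 0.703 with an estimated correlation) and with the length trend removed (0.863, at a median of 0.05; range over the alternatives 0.00245 to 0.863).

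Genes of lipid handling fell in part, in the libraries where neutrophil and monocyte markers rose by medians of 5.42 and 1.14 on the log2 scale. Of 20 scavenger receptor and lipid loading genes, 13 fell and 5 rose (13 and 7 adjusted over the list alone; camera adjusted p = 0.011; adjusted p = 0.133 with an estimated correlation, which ends the call). Lipa, the lysosomal acid lipase gene, fell from 1756 ± 94.2 to 338 ± 29.7 CPM and Nceh1 from 426 ± 25.9 to 170.2 ± 1.13 CPM, whereas Hilpda, a lipid droplet gene, rose 10.7-fold. Of 17 LXR targets and cholesterol efflux genes, 10 fell and 4 rose, also adjusted over the list alone (camera adjusted p = 0.0216; adjusted p = 0.355 with an estimated correlation, which ends the call). The sterol exporter gene Abcg1 fell from 129.9 ± 4.34 to 37.3 ± 1.51 CPM and Pltp from 249.8 ± 12.9 to 55.8 ± 6.86 CPM. Of 24 sterol synthesis genes, 18 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00284; adjusted p = 0.133 with an estimated correlation, which ends the call). Cyp51 rose 3.08-fold, Fdft1 3.07-fold and Insig1 2.29-fold. Of 21 fatty acid synthesis genes, 9 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.968), with Dgat2 9.35-fold higher. Of 12 genes of trimethylamine oxide, choline and carnitine metabolism, 5 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.622), with the choline kinase gene Chka 2.34-fold higher and Pcyt1a at a log2 fold change of -1.77.

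Coagulation genes rose: 11 of 18 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 1.03e-05; adjusted p = 0.133 with an estimated correlation, which ends the call). Serpinb2, a plasminogen activator inhibitor gene, rose from 2.28 ± 0.777 to 128 ± 25.4 CPM, the urokinase receptor gene Plaur 4.94-fold and F10 3.94-fold. F13a1, which rose 20.2-fold, is in both the coagulation list and that of monocyte markers, whose median log2 fold change in the same libraries was 1.14, against 5.42 for neutrophil markers. Of 27 matrix and matrix protease genes, 11 rose and 8 fell, also adjusted over the list alone (camera adjusted p = 0.144), with Thbs1 9.63-fold and Mmp13 4.65-fold higher. All 6 libraries held Y-linked counts, with 1512 to 3251 counts of Ddx3y, and 4 to 20 counts of Xist. Of the 4 sex-linked genes tested, Eif2s3y rose 2.02-fold and the other 3, among them Uty, fell, also adjusted over the list alone.

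**Figure D3:**
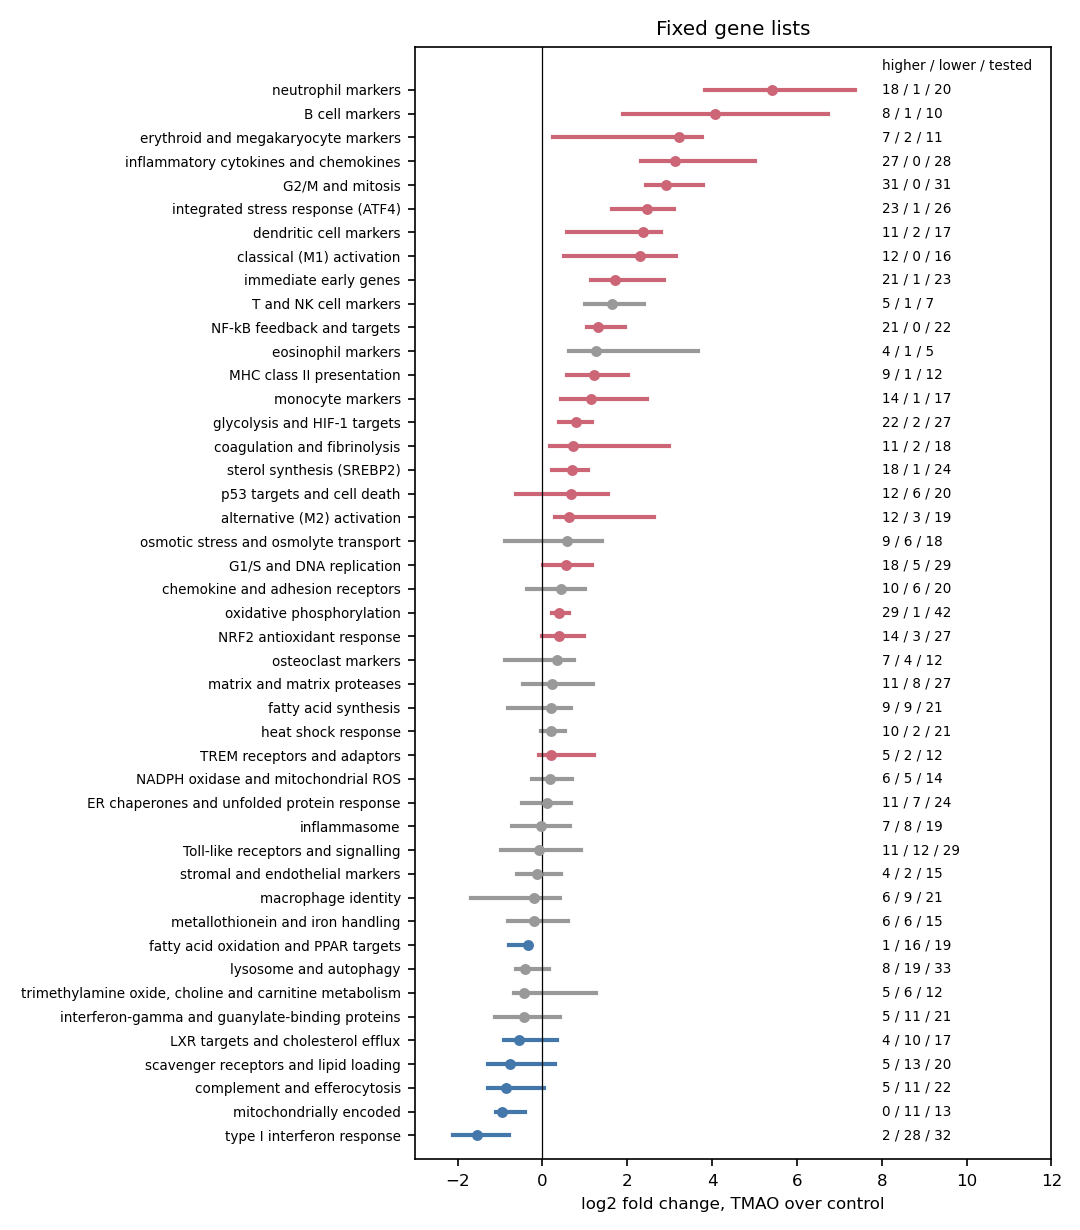
Median log2 fold change (point) and quartiles (line) of the members of the 45 gene lists tested, TMAO over control, with the numbers of members higher, lower and tested at the right; red and blue are lists called higher and lower by camera with its preset correlation, grey lists were not called. The medians of called lists run from -1.54 for type I interferon response genes to 5.42 for neutrophil markers.

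Of the 45 lists tested, 27 were called by camera with a preset correlation of 0.01, 21 higher and 6 lower. With an estimated correlation 7 were called: inflammatory cytokines and chemokines, NF-kB feedback and targets, alternative activation, the integrated stress response, G2/M and mitosis, immediate early genes, and neutrophil markers. By fry, which tests whether a list's genes move on balance one way, 42 lists were called. The median and the camera direction differed in sign in 4 lists, none of them called: inflammasome, Toll-like receptor, osteoclast and fatty acid synthesis. The mean and the camera direction did so in the Toll-like receptor, osteoclast, fatty acid synthesis, metallothionein and trimethylamine oxide lists, none of them called.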

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

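The GC correction, the newer quasi-likelihood moderation and the list tests with length or GC trends removed were chosen after the data were seen; the other alternatives were planned. The number of genes changed was 8754 to 10038 over the settings that kept all libraries and 8629 to 9931 with 1 library left out, against 9608. At least 2-fold, the ranges were 3531 to 5000 and 4196 to 4964, against 4448; a test against a fold of 1.5 called 5184 genes. Trem1 kept its direction and call throughout, with log2 fold changes of 5.94 to 6.02, and 5.74 to 6.11 with 1 library left out, as did Nlrp3 with 2.72 to 2.93 and 2.67 to 2.89. The newer moderation called 9735 genes, 9604 of them shared. With the length trend removed, 9618 genes were called, of which 8147 were shared and 8068 had the same direction. Of 156 named genes, 152 kept direction and call in every setting that tested them; the exceptions were Pycard, Casp1, Il18 and Gsdmd. Il18 reversed, without being called, with the length trend removed (-0.1173) and with the replicate block and the length trend removed (-0.1213); the cause was not tested. Of 45 lists, 27 were called, against 7 with an estimated correlation and 42 by fry, which does not set a list against other genes; the other settings gave 26 to 31. Setting those 2 tests aside, 34 lists kept their call in every setting and 11 did not, and none reversed. Of the called genes in lists, 44 of 703 were in more than 1 list. Same-numbered libraries deviated from their group means with r = 0.032, 0.133 and -0.067, and not every library correlated best with its own number, so the numbers do not pair the samples. The replicate block called 9723 genes, 4457 at least 2-fold, and 29 lists. Among them, called lower with the block but not in the main fit, were macrophage identity (camera adjusted p = 0.028) and the interferon-gamma list (0.0459). Some other settings also called these lists lower. For genes near the floor of 3 counts over a group, depth limits the fold to a bound or a wide interval.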

Other observations

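The tests of scaling and of macrophage dilution were chosen after the results they bear on were seen, and the 7 gene lists used here were written after the first results were seen but before their own values were examined. Most genes tested from 3 lists of protein synthesis rose in the TMAO libraries, where all 31 G2/M genes rose too and neutrophil markers were higher by a median of 5.42 on the log2 scale. Of 37 ribosomal protein genes tested, all 37 rose, with a median log2 fold change of 1.04 (camera adjusted p = 6.1e-08). That call was lost with an estimated correlation (adjusted p = 0.309 with an estimated correlation), and the median was 0.70 with the length trend removed. Rplp0 went from 1246 ± 170.3 to 2579 ± 182 CPM (mean ± SD, n = 3 per group), and Rps6 rose 2.47-fold. Of 24 ribosome biogenesis genes and MYC targets, 23 rose and none fell (camera adjusted p = 9.09e-11; adjusted p = 0.0181 with an estimated correlation). Odc1, the first enzyme of polyamine synthesis, rose 12.4-fold and Nop56, a nucleolar protein gene, 3.02-fold. Of 18 aminoacyl-tRNA synthetase genes, which ATF4 also drives, 15 rose and 1 fell (camera adjusted p = 4.78e-05; adjusted p = 0.157 with an estimated correlation, which ends the call), with Yars 3.05-fold higher. Both replication-dependent histone genes that were tested rose, but they were near the floor and too few for a list test. Hist1h2ac went from 0.00858 to 0.457 CPM and Hist1h4d from 0.182 to 0.732 CPM. Of 13 microglia-like and tissue macrophage genes, 6 rose and 3 fell, and the list was not called (camera adjusted p = 0.0765), although Fcrls rose from 11.9 to 185 CPM.

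Abundant macrophage transcripts did not move together; these genes were chosen after their values were seen. Apoe, an LXR target, rose from 7529 ± 736 to 15284 ± 1444 CPM while Abcg1 and Abca1 fell, with log2 fold changes of -1.80 and -0.61. The macrophage genes Mpeg1 and Adgre1 fell with log2 fold changes of -1.70 for each, whereas Lyz2 was at 37023 ± 2335 and 37357 ± 4499 CPM and did not pass the test. B2m, the light chain of MHC class I, fell from 7386 ± 439.5 to 2682 ± 242 CPM, while C1qb rose 1.60-fold.

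Granulocyte precursor genes were higher in all 3 TMAO libraries, with Ngp, S100a9 and S100a8 the most abundant at 1164, 1851 and 733 CPM against 7.50, 17.4 and 22.8 CPM. The library scalings run do not account for it, since they left the median log2 fold change of all genes between -0.0234 and 0.0358. A large drop of the neutrophil markers was therefore not possible, and their median of at least 5.076 in the scaling test adds nothing to this. Of 21 tested granulocyte genes outside the fixed lists, 14 rose and 3 fell (66.7% higher; camera adjusted p = 4.85e-07; adjusted p = 0.102 with an estimated correlation), and 7 of the 21 were at 5 CPM or more in controls. Of 19 blood progenitor genes, 13 rose and 5 fell (68.4% higher; camera adjusted p = 0.0275; adjusted p = 0.185 with an estimated correlation), 4 of the 19 were at 5 CPM or more in controls, and 3 belong to fixed lists. The 3 granulocyte genes that fell, Clec12a, Hk3 and Ly6i, were at 525, 320 and 77.6 CPM in controls. Anxa3, Orm1, Adam19 and Mmp25, at 173, 5.88, 4.82 and 0.905 CPM there, did not pass, and Mcemp1 and Mgst2, at 28.1 and 12.5 CPM, rose. Genes that the controls already express are weak markers of added cells, so the shares are hard to read. The 4 progenitor genes at 5 CPM or more in controls did not rise: Cd48, Cdk6 and Tal1 fell and Lmo2 did not pass. Genes nearly silent in controls, such as Ms4a3 and Myct1 (0.0333 and 0.0494 CPM), could pass the count filter only through the TMAO libraries. Their rise was therefore fixed in advance, as was that of neutrophil markers such as Mpo. Both shares lay between the bounds set beforehand, 50% against and 70% for the cells, but for this reason they cannot decide the question. Granulocyte-lineage cells or progenitors in the treated cultures may be a source. They cannot be told apart from induction of these genes by TMAO, which the design confounds with them and which was not tested.

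Interferon-stimulated genes were lower in the TMAO libraries. Their median log2 fold change stayed at -1.461 or below in the scaling test, an outcome that the small differences between the scalings fixed in advance. Dilution of macrophages by other cells could lower the interferon genes, but it would lower macrophage identity genes alike. The median of the 21 macrophage identity genes lay 1.35 above that of the interferon genes on the log2 scale (two-sided permutation over genes, p = 0.006), with 6 genes higher and 9 lower. The permutation takes genes as independent, although the correlation estimated within the interferon list was 0.72. Its p does not measure the spread between libraries. An earlier bound of 0.5 would have counted this difference against dilution. The bound was widened after the value was seen, to the interquartile range of the macrophage identity genes, because these moved both ways. That range was 2.10, wider than the difference, so dilution and a lower interferon response with TMAO cannot be told apart here.

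Trem1 and the inflammatory cytokines were higher in the TMAO libraries. In the scaling test the median of the cytokine list was at least 3.032 and Trem1 at least 5.943, which the small differences between the scalings also fixed in advance. Neutrophils and monocytes express Trem1, so cells of the granulocyte lineage may bring part of its transcripts. If so, the TMAO libraries with more neutrophil transcripts would hold more Trem1, but the median level of the neutrophil markers differed by only 0.299 on the log2 scale between the TMAO libraries, and that of Trem1 by 0.206. This range is too small to decide, so such cells and a response of the cells to TMAO cannot be told apart.

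The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. Only the real split, 1 of 10, gave as many as 9608 genes, 4448 genes at least 2-fold and 27 lists. The highest other split gave 0, 0 and 20. Each remaining split mixes control and TMAO libraries in both of its groups, so the difference between treatments becomes spread within groups. Few or no genes could pass there, so these splits cannot measure chance. In them, camera with its preset correlation still called 11 to 20 lists although no gene passed. The number of lists it calls is therefore weak evidence alone. The median log2 fold change ran from 0.49 to -0.53 from the shortest to the longest 20% of genes, and from -0.29 to 0.27 from the lowest to the highest GC content.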
